A study of Homo sapiens with 4 samples.

How the data were processed

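RNA was measured by sequencing in 4 libraries of 293FT cells, a fast-growing line derived from human embryonic kidney 293 cells that carries the SV40 large T antigen. 2 libraries were labelled NIPBL wild type and 2 NIPBL mutant, numbered replicate 1 and 2 in each group. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-specific libraries. Per the submitters' processing notes, STAR 2.7.3a and RSEM 1.3.1 were used with the hg38 build. The annotation release and the strand setting of the counting are not given in the sources used here. Reads from a gene and an overlapping gene on the other strand may therefore not have been told apart. Some genes named below also overlap another annotated gene on the same strand, among them KLHL41, HOXA6, HOXB6, HSPE1, ATP5MF, SNORA73A and SNORA73B. How shared reads were divided there was not checked.

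The authors deposited 1 table per library with 58174 genes. Per the file headers, each table gives expected counts, which are RSEM's estimates of the reads per gene and need not be whole, together with TPM, which are transcript abundances scaled by effective length to a fixed total. The deposited effective lengths were used in 1 alternative, and the authors' FPKM values were not used. The deposited expected counts summed to 31545743 and 33161120 in wild-type replicates 1 and 2 and to 31932304 and 32768728 in mutant replicates 1 and 2. At this depth 1 count corresponded to between 0.0287 and 0.0335 CPM, which are counts scaled to a common library total. Where a group had no counts, the fold was computed against 3 counts per library and is a lower bound that covers counting error only. The gene identifiers were matched without their version to GENCODE release 29 (GRCh38), where 57836 of the 58174 were found. Coordinates are those of that annotation.

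From these files, expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, libraries were scaled by trimmed mean of M values (TMM), and robust quasi-likelihood tests compared mutant with wild type. P-values were adjusted by Benjamini-Hochberg over the 18984 tested genes and called under 0.05. Levels are TMM-scaled CPM, given as mean ± SD over the 2 libraries of a group, and log2 fold changes are mutant over wild type with their standard error (SE). The labels do not say that the libraries came from separate cultures or clones, so p-values measure the spread between these samples, which may be technical. The replicates were compared first. The chi-square per gene was 47.2 for the wild-type pair and 4.0 for the mutant pair, against 1 for 1 library counted on both occasions, so each library was counted as a sample.

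Before the data were examined, 32 gene lists were fixed, and the 28 with at least 5 tested members were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01. The same lists were tested with an estimated correlation and with fry, and each list's genes were also adjusted over the list alone. The genes named in the text were set by a rule of the same date. They are NIPBL, every member of the cohesin list, the 12 largest and 12 smallest log2 fold changes among called protein-coding genes of at least 5 CPM whose groups did not overlap, and up to 4 members of each list with the smallest p, at most 2 in each direction. Not every gene that met this rule is reported. Gene span was related to fold change by Spearman correlation across genes, chromosomes were tested with camera, and adjacent called genes were counted against 1000 permutations of the calls within chromosomes.

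The alternatives were other scalings (RLE, upper quartile, total count), no filter or a stricter one, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), effective length offsets, leaving out small RNA and mitochondrial genes, a replicate block, leaving out each library, and a test against a 1.2-fold change. Regions of 10 Mb with at least 15 tested genes, and a fit that removes the median fold change of the 25 tested protein-coding genes on each side of a gene (the neighbourhood offset), were chosen after seeing the data.

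The test was checked on simulated data for this comparison, with counts for the 18984 genes drawn 10 times and 200 genes changed in each draw. Draws used the real library sizes, each gene's mean over all libraries and a dispersion per gene shared by both groups. The simulated groups thus had equal spread, unlike the real wild-type and mutant pairs, so the shares below may differ for the real data. Of 500 genes changed per fold size, 9.2% were recovered at 1.5-fold, 48.6% at 2-fold, 83% at 4-fold and 96.4% at 8-fold. Of 1378 calls 192 were false, or 13.9%, which is above the 5 percent that the threshold aims at.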

Results

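The series measured transcription in 293FT cells with wild-type or mutant NIPBL, the gene for the protein that loads cohesin onto chromosomes. Its title names Cornelia de Lange and CHOPS syndromes, and the comparison asks which transcripts differ between the 2 genotypes. The kind of mutation and the number of clones are not given in the labels. The expected counts summed to 31545743 and 33161120 in the wild-type and to 31932304 and 32768728 in the mutant libraries, and between 26629 and 28663 genes had a count above 0 per library. Over the tested genes, log2 CPM correlated at 0.992 between the mutant libraries, at 0.981 between the wild-type libraries and at 0.955 to 0.971 between genotypes, as Pearson's r across genes, which are not independent replicates.

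NIPBL (ENSG00000164190, chromosome 5, 36876759 to 37066413, plus strand) was at 43.1 ± 1.87 CPM in wild type and 61.5 ± 0.658 CPM in mutant libraries (SD, n = 2 each). The log2 fold change of 0.51 (SE 0.11) had an edgeR adjusted p of 0.057 and was not called. It lay near the median of 0.42 over the 25 tested protein-coding genes on each side of NIPBL. Since the kind of mutation is not stated, this level does not check the labels. NIPBL passed the threshold with upper-quartile scaling (0.60, adjusted p = 0.0384), total counts (0.69), the stricter filter (0.53) and DESeq2 (0.50). Its log2 fold change was 0.45 without wild-type replicate 1 and 0.55 without replicate 2.

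Of the 16 cohesin subunits and regulators none was called by edgeR, over all genes or adjusted over the list alone, while 4 had an unadjusted p under 0.05 and DESeq2 called 2, NIPBL and STAG1. In alternatives edgeR called both with upper-quartile scaling and total counts, and STAG1 with no filter (adjusted p = 0.0486) and the replicate block (0.0211). Fits without 1 wild-type replicate take their spread from the mutant pair alone, so calls there are not counted as support. Those without 1 mutant replicate take it from the wider wild-type pair alone, so a call lost there does not show dependence on that replicate. The list median was -0.175 without wild-type replicate 1 and 0.056 without replicate 2. STAG1, a cohesin subunit, was at 110 ± 27.0 CPM in wild type and 185 ± 7.38 CPM in mutant. Its log2 fold change was 0.75 (SE 0.19, edgeR adjusted p = 0.0751, DESeq2 adjusted p = 0.00688). The fold change was 0.50 without wild-type replicate 1 and 1.02 without replicate 2. The cohesion acetyltransferase ESCO2 had -0.48 and the cohesin regulator PDS5B -0.43. The core ring genes SMC1A, SMC3 and RAD21 had 0.28, 0.22 and -0.16, and STAG2 and the NIPBL partner MAU2 both had 0.18. PDS5A had -0.34 (-0.15 without wild-type replicate 2 and -0.52 without replicate 1), CTCF -0.29, WAPL -0.18, HDAC8 -0.17 (-0.04 and -0.30), CDCA5 -0.10, ESCO1 0.07 and SGO1 -0.04. The list median was -0.07 and the camera adjusted p was 0.913 (adjusted p = 0.974 with an estimated correlation).

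Across the transcriptome, 704 genes were higher and 399 lower in the mutant libraries, 573 and 129 of them by at least 2-fold. The groups did not overlap at any of these 1103 genes, nor at 63.2% of all tested genes. By chance 33.3% would not overlap if all 4 libraries varied alike. The mutant pair was closer than the wild-type pair (chi-square per gene 4 against 47.2), which raises the share expected without a genotype effect. The 63.2% is therefore not a measure of such an effect. The higher genes had a median log2 fold change of 2.02, and 68.2% of them were under 5 CPM in wild type. The lower genes had a median of -0.85, and 8.5% of them were under 5 CPM in wild type. A split by wild-type level favours such a gap, since a lower gene needs a level to fall from. Among called protein-coding genes, 272 higher ones were under 1 CPM in wild type and 21 lower ones under 1 CPM in mutant. Higher genes made up 63.8% of calls, and 80.2% with total counts, 87.3% with limma-trend on TPM and 52.4% with DESeq2. The median over the tested genes moved to 0.17 with total counts and 0.12 on TPM. Leaving out mutant replicate 1 or 2 gave fewer calls in each direction, since the spread then came from the wider wild-type pair alone. None of the 1103 called genes that were still tested changed sign in these fits. Leaving out wild-type replicate 1 or 2 gave 5909 or 4287 higher and 5931 or 4033 lower, since the spread then came from the close mutant pair alone. In simulated data with 200 changed genes per draw 13.9% of calls were false. That share depends on how many genes truly change, and the simulated groups had equal spread, unlike the real pairs. The share need not hold for the 1103 calls.

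Among called protein-coding genes with a mean of at least 5 CPM, the largest rises were in genes low in wild type. GDA, guanine deaminase, had no counts in wild type and 10.8 ± 0.785 CPM in mutant, at least 110-fold higher. HAS2, a hyaluronan synthase, rose from 2.15 ± 1.197 to 58.2 ± 5.00 CPM (log2 fold change 4.75, SE 0.36, adjusted p = 0.013). The adhesion gene CDH11 rose by 6.22, the keratin KRT17 by 5.06 and the sodium leak channel NALCN by 4.71 on the log2 scale. TMEM132B (5.37), NELL1 (5.21), MACC1 (4.82), ASTN1 (4.75), CHIT1 (3.71) and KCNS3 (3.58) were also among the 12 largest. These genes stayed called in every alternative run in which they were tested, by edgeR, DESeq2 and limma.

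Under the same conditions the deepest fall was in NEFM, a neurofilament subunit, from 68.3 ± 6.29 to 1.08 ± 0.352 CPM (log2 fold change -5.98, SE 0.24, adjusted p = 0.0086). GLA, the lysosomal alpha-galactosidase, fell from 458 ± 9.34 to 94.4 ± 5.51 CPM (-2.28, SE 0.12), and the transporter ABCB6 fell from 14.99 ± 0.322 to 0.817 ± 0.0582 CPM (-4.19). Monoamine oxidase A, MAOA, had -2.61 and the zinc finger gene ZNF331 -2.78. KLHL41 (-2.05), NAT8L (-1.64), HOXA6 (-1.61), ATAD3B (-1.61), HSPE1 (-1.59) and HOXB6 (-1.57) were also among the 12 smallest. RGPD6 (-2.01) and ATAD3B have near-identical copies, so their counts are uncertain, and RGPD6 had -0.44 (adjusted p = 0.134) with effective length offsets. HOXA6 lost its call without mutant replicate 1 (adjusted p = 0.093) or replicate 2 (0.0561), and NAT8L, ATAD3B, HSPE1 and RGPD6 lost theirs with the neighbourhood offset, where they still had -1.12 (SE 0.26), -1.29 (SE 0.27), -1.01 (SE 0.26) and -1.69 (SE 0.36). They also lost them with limma-trend on TPM, at -1.10, -1.32, -1.39 and -0.22 (adjusted p from 0.0506 to 0.314).

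**Figure D1:**
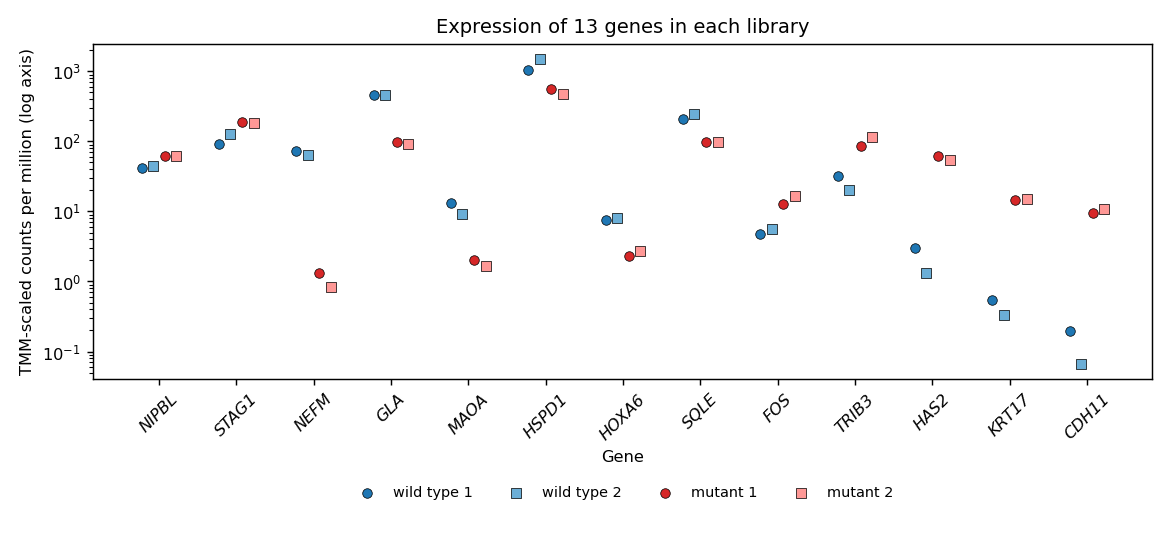
TMM-scaled CPM on a log axis for 13 genes, with 1 point per library (circles replicate 1, squares replicate 2; blue wild type, red mutant). NIPBL lies at 43.1 CPM in wild type and 61.5 in mutant on average, NEFM at 68.3 and 1.08, and GLA at 458 and 94.4.

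Of 38 HOX genes, which pattern the body axis, 7 were called lower and none higher by edgeR, and 12 lower when adjusted over the list alone. HOXA6 went from 7.76 ± 0.345 to 2.53 ± 0.277 CPM and HOXD11 from 25.4 ± 1.16 to 11.5 ± 0.528 CPM (log2 fold change -1.15, adjusted p = 0.0257; 0.0682 without mutant replicate 2). The list median was -0.61 (camera adjusted p = 9.53e-07; adjusted p = 0.517 with an estimated correlation). HOXD11 lies where neighbouring genes had a median of -0.53 and was not called with the neighbourhood offset (-0.62, adjusted p = 0.071), while 5 HOX genes were lower with the neighbourhood offset.

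Neuronal genes moved both ways, with 7 of 25 higher and 1 lower (13 and 4 adjusted over the list alone). The granin CHGB rose from 1.94 ± 0.134 to 15.6 ± 1.41 CPM (log2 fold change 3.01), while NEFM fell. The list median was 0.72 (camera adjusted p = 0.000515; adjusted p = 0.517 with an estimated correlation). Keratin and squamous markers had 3 of 8 higher and none lower (5 adjusted over the list alone), led by KRT17. Their median was 1.40 (camera adjusted p = 2.25e-06, or 0.517 with an estimated correlation). Only these 8 of the 16 listed genes passed the filter, which a gene low in wild type can do through its mutant level. All tested protein-coding genes under 1 CPM in wild type had a median of 1.12, so the rise of this list may be partly built in. Of the 16 markers of the kidney line, KRT8 rose by 0.83 and NEFM, LIN28B and VIM fell (1 and 5 adjusted over the list alone; camera adjusted p = 4.73e-05; adjusted p = 0.517 with an estimated correlation). KRT8 was not called without mutant replicate 1 (adjusted p = 0.174) or replicate 2 (0.128), nor LIN28B without replicate 2 (0.0652). The median of this list was -0.30, and -0.46 without wild-type replicate 1. With the neighbourhood offset LIN28B (-1.04) and VIM (-0.54) were not called (adjusted p = 0.0557 and 0.0732). VIM was named after its values were seen.

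Extracellular matrix and TGF-beta genes had 5 of 33 higher and 2 lower (11 and 3 adjusted over the list alone). COL12A1 rose from 2.38 ± 0.179 to 7.17 ± 0.0157 CPM and LTBP1 from 29.1 ± 5.08 to 63.4 ± 0.515 CPM, while the integrin ITGAV fell by 0.82 and COL3A1 by 2.04 on the log2 scale. The list was called (median 0.45, camera adjusted p = 0.0047; adjusted p = 0.517 with an estimated correlation), with a median of 0.68 without wild-type replicate 1, but not without wild-type replicate 2 (0.10, adjusted p = 0.337) or with limma-trend on TPM (0.39, adjusted p = 0.115). Of 14 fibroblast markers 10 passed the filter, which low genes can do through their mutant level, so a rise may be partly built in. Of these 10, 2 were higher, PDGFRB and LUM, and COL3A1 was lower (5 and 1 adjusted over the list alone). Fibroblast markers had a median of 0.72 (camera adjusted p = 0.0171, or 0.517 with an estimated correlation). Their call was lost without wild-type replicate 1 (adjusted p = 0.067) or replicate 2 (0.366), with total counts (0.0538), the stricter filter (median 0.42, adjusted p = 0.0504), limma-trend on TPM (median 0.37, adjusted p = 0.165) and effective length offsets (0.0857). COL12A1, ITGAV and LUM were not called without mutant replicate 1 or replicate 2 (adjusted p from 0.0728 to 0.246), nor COL3A1 without mutant replicate 1 (0.0909). COL3A1 was also not called with upper-quartile scaling, total counts, the stricter filter, limma-voom or limma-trend on TPM (adjusted p from 0.0506 to 0.0675), nor COL12A1 on TPM (0.0617) or with effective length offsets (0.0539), nor ITGAV on TPM (0.0793). With the neighbourhood offset LTBP1 had 0.73, ITGAV -0.42 and COL3A1 -1.59, none of the 3 called by edgeR (adjusted p = 0.071, 0.143 and 0.089).

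Immediate early genes, which respond within minutes to growth signals, had 4 of 20 higher and none lower (8 adjusted over the list alone): DUSP1, EGR1, FOS and JUN. DUSP1 rose from 18.7 ± 2.61 to 41.9 ± 4.88 CPM and FOS from 5.16 ± 0.602 to 14.7 ± 2.95 CPM, the latter not called without mutant replicate 2 (adjusted p = 0.0949). The list median was 0.55 (camera adjusted p = 0.00114; adjusted p = 0.517 with an estimated correlation). EGR1 and JUN were named after their values were seen.

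Cholesterol synthesis genes had 5 of 23 lower and none higher (11 adjusted over the list alone). SQLE, squalene epoxidase, fell from 226 ± 25.4 to 98.1 ± 0.948 CPM and IDI1 from 193 ± 25.9 to 79.6 ± 1.04 CPM. The list median was -0.47 (camera adjusted p = 3.3e-08; adjusted p = 0.517 with an estimated correlation). With the neighbourhood offset 3 were lower.

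Ribosomal protein genes had 12 of 80 lower and none higher (29 adjusted over the list alone). RPL7 fell from 1359 ± 29.3 to 747 ± 7.01 CPM and RPS6 from 1918 ± 2.01 to 1079 ± 17.4 CPM. The median was -0.28 (camera adjusted p = 6.09e-10; adjusted p = 0.517 with an estimated correlation). With total counts it was -0.11, with 7 genes lower, and on TPM -0.07, also with 7. Nuclear oxidative phosphorylation genes had 8 of 74 lower (13 adjusted over the list alone), among them the ATP synthase subunits ATP5ME (-0.87) and ATP5MF (-0.80), and a median of -0.21 (camera adjusted p = 3.17e-05; adjusted p = 0.517 with an estimated correlation). The oxidative phosphorylation median was -0.13 without wild-type replicate 2 and 0.018 on TPM, where the list was still called down. With the neighbourhood offset 5 ribosomal and 1 oxidative phosphorylation genes were called lower, while RPL7 (-0.43), RPS6 (-0.57), ATP5ME (-0.28) and ATP5MF (-0.46) were not (adjusted p from 0.0521 to 0.198). RPL7, RPS6, ATP5ME and ATP5MF were not called without mutant replicate 1 or replicate 2 (adjusted p from 0.143 to 0.282).

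Of 17 heat shock genes 3 were called lower over all genes by edgeR, and 13 when adjusted over the list alone. The mitochondrial chaperonins HSPD1 (1260 ± 323 to 519 ± 62.5 CPM) and HSPE1 and the HSP110 gene HSPA4L (-1.22) fell. The list median was -0.87 (camera adjusted p = 3.3e-08; adjusted p = 0.517 with an estimated correlation). Wild-type replicate 2 exceeded replicate 1 by a median of 0.75, and the mutant mean lay 0.53 below replicate 1 and 1.22 below replicate 2. HSPA1A, chosen after its values were seen, had 732 and 2741 CPM in wild type and 263 and 232 CPM in mutant (edgeR adjusted p = 0.0582). HSPD1 was not called without mutant replicate 2 (adjusted p = 0.0553). Without wild-type replicate 2 the median was -0.53. With the neighbourhood offset HSPD1 had -0.70 and HSPE1 -1.01, neither called (adjusted p = 0.127 and 0.103).

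Ribosome biogenesis genes had 2 of 28 lower, NOP58 (-1.09) and WDR12 (-1.004), and 5 adjusted over the list alone. The list median was -0.55 (camera adjusted p = 3.17e-05, or 0.581 with an estimated correlation). WDR12 was not called with limma-trend on TPM (-0.84, adjusted p = 0.056). ATF4 and amino acid response genes had 1 of 24 higher (also 1 adjusted over the list alone), TRIB3, from 26.4 ± 8.43 to 101 ± 20.4 CPM, and a median of 0.57 (camera adjusted p = 0.000599; adjusted p = 0.581 with an estimated correlation). Wild-type replicate 2 minus 1 was 0.66 for the first list and -1.15 for the second. The medians were -0.08 and 0.08 without wild-type replicate 2 and -0.90 and 1.43 without replicate 1, and TRIB3 was not called without wild-type replicate 1 (adjusted p = 0.108) or replicate 2 (0.182). NOP58 and WDR12 were not called without mutant replicate 1 or replicate 2 (adjusted p from 0.0634 to 0.139), nor with the neighbourhood offset (-0.55 and -0.52, adjusted p = 0.167 and 0.153).

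**Figure D2:**
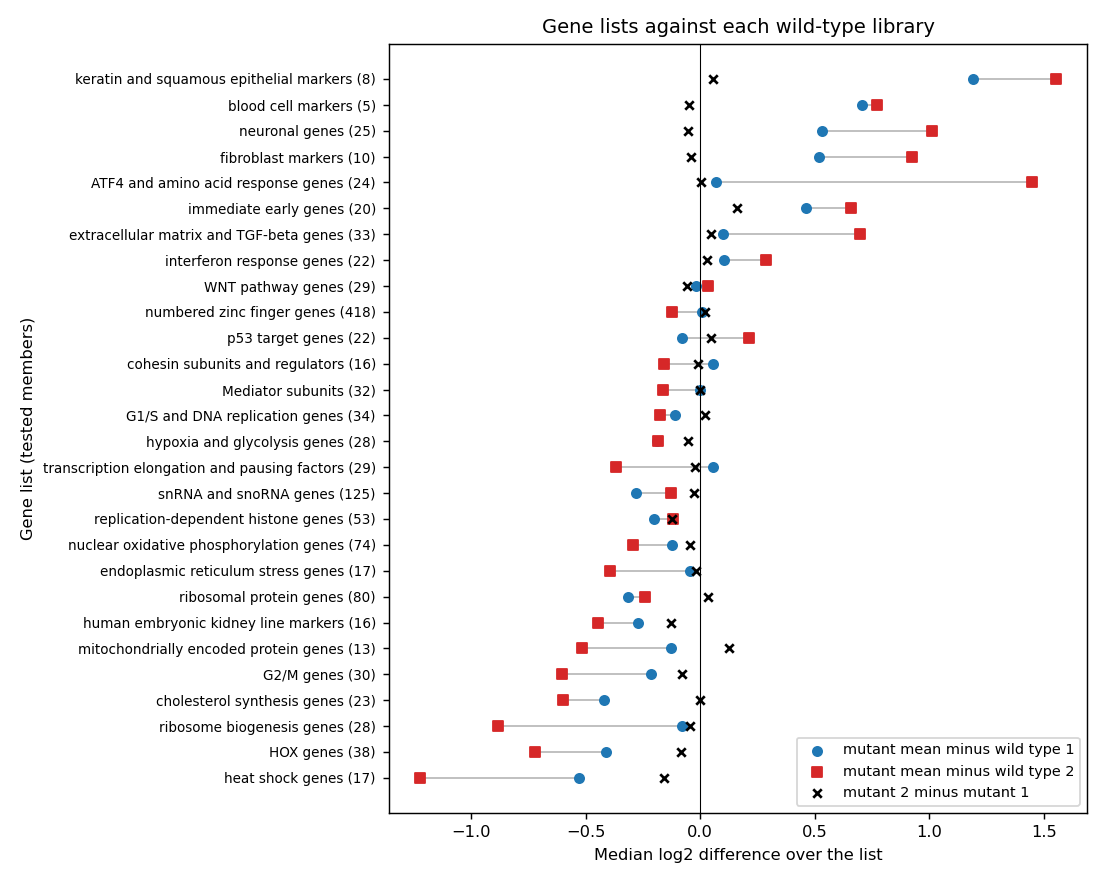
Median log2 difference over the tested members of each of 28 gene lists: mutant mean minus wild-type replicate 1 (blue circles), mutant mean minus wild-type replicate 2 (red squares) and mutant replicate 2 minus 1 (crosses). The ATF4 list lies at 0.07 against wild-type replicate 1 and 1.45 against replicate 2, and the cholesterol list at -0.42 and -0.60.

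G2/M genes had 3 of 30 lower, TACC3, CENPF (-0.78) and KIF2C (-0.61), with the same number adjusted over the list alone and a median of -0.42, or -0.22 without wild-type replicate 2 (camera adjusted p = 1.94e-05; adjusted p = 0.517 with an estimated correlation). G1/S and replication genes had RFC4 higher (0.65) and MCM6, MCM4 and SLBP lower among 34 (1 and 5 adjusted over the list alone; median -0.10, or -0.19 without wild-type replicate 1, camera adjusted p = 0.0166; adjusted p = 0.517 with an estimated correlation), and that call was lost with total counts (median 0.07, adjusted p = 0.082) and with limma-trend on TPM (median 0.08, adjusted p = 0.0966). None of these 7 genes was called by edgeR with the neighbourhood offset, where CENPF had -0.62 (SE 0.12), TACC3 -0.47 (SE 0.19; -1.02 without the offset), KIF2C -0.41 (SE 0.11), MCM4 -0.33 (SE 0.11), SLBP -0.21 (SE 0.12), MCM6 -0.14 (SE 0.11) and RFC4 -0.11 (SE 0.12). CENPF, KIF2C, RFC4, MCM6 and SLBP were not called without mutant replicate 1 or replicate 2 (adjusted p from 0.2 to 0.512), nor were CENPF, KIF2C, MCM6 and SLBP with limma-trend on TPM (0.053 to 0.094), KIF2C and MCM6 with total counts (0.0539 and 0.0685) or MCM6 with upper-quartile scaling (0.0537). TACC3 and MCM4 were named after their values were seen. Replication-dependent histone genes had 3 higher, led by HIST1H2AE (1.27), and 5 lower, among them HIST2H3D (-0.91), of 53 (3 and 13 adjusted over the list alone; median -0.21, camera adjusted p = 0.00511; adjusted p = 0.558 with an estimated correlation), and the list lost its call without mutant replicate 2 (adjusted p = 0.0988) and had a median of -0.13 without wild-type replicate 1. Of 125 snRNA and snoRNA genes 4 were lower, SNORA73A (-0.83) and SNORA73B (-0.85) among them (2 adjusted over the list alone; median -0.19, camera adjusted p = 0.00114; adjusted p = 0.517 with an estimated correlation), and the call was lost without wild-type replicate 1 (adjusted p = 0.445) and with DESeq2 (adjusted p = 0.0858). The snRNA and snoRNA median was 0.012 on TPM. HIST2H3D, SNORA73A and SNORA73B were not called without mutant replicate 1 or replicate 2 (adjusted p from 0.129 to 0.234).

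The planned second list test, fry, gave an adjusted p under 0.05 for none of the 28 lists (lowest 0.0755), and an unadjusted p under 0.05 for 9 of the 17 lists called by camera and 2 of the other 11. It gave 0.118 for heat shock, 0.144 for G2/M, 0.253 for ATF4 and 0.295 for ribosome biogenesis genes, unadjusted.

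The remaining lists were not called by camera in the planned test, though some were in alternatives. The elongation list was called with no filter (adjusted p = 0.0217), DESeq2 (0.0103), effective length offsets (0.0407), the replicate block (0.0434), the neighbourhood offset (0.0424), and without wild-type replicate 1 (median -0.38, adjusted p = 0.00168) or mutant replicate 1 (0.0365), while its median was 0.055 without wild-type replicate 2, 0.027 with total counts and 0.059 on TPM. The mitochondrially encoded list was called with no filter (0.0144), DESeq2 (0.0199), limma-voom (0.0466), the neighbourhood offset (0.0396) and without mutant replicate 2 (0.0302). The hypoxia list was called with no filter (0.0435), DESeq2 (0.0337) and without wild-type replicate 2 (0.0102), and the interferon list with no filter (0.0153), DESeq2 (0.0489) and the neighbourhood offset (0.015). Endoplasmic reticulum stress genes were called without wild-type replicate 1 (0.0213), and zinc finger genes without mutant replicate 2 (0.0381) and with the neighbourhood offset (0.0396). Elongation and pausing factors had NELFA lower (-0.66; 2 adjusted over the list alone; camera adjusted p = 0.0657), and Mediator subunits had MED28 lower (-0.57; none adjusted over the list alone; camera adjusted p = 0.262). NELFA, MED28, IFIH1, IRF7, NKD2, FZD3 and FZD7 were not called without mutant replicate 1 or replicate 2 (adjusted p from 0.0914 to 0.491), nor TP53I3 without replicate 2 (0.0614) or FGG without replicate 1 (0.051). With the neighbourhood offset NELFA had -0.11, MED28 -0.45, TP53I3 0.53, NKD2 0.54, FZD3 -0.37, FZD7 -0.38 and ISG20 1.48, none of the 7 called by edgeR (adjusted p from 0.0653 to 0.611). NELFA and MED28 were also not called with upper-quartile scaling, total counts or limma-trend on TPM (adjusted p from 0.0516 to 0.0993), nor NELFA with effective length offsets (0.0516) or MED28 with the replicate block (0.0523). NKD2 was not called with upper-quartile scaling, limma-trend on TPM or effective length offsets (0.0516, 0.0531 and 0.0637), nor FZD7 and FZD3 on TPM (0.0584 and 0.0749). Interferon response genes had 3 of 22 higher (3 higher and 1 lower adjusted over the list alone), IFIH1 (1.21), IRF7 (1.24) and ISG20, the last named after its values were seen (camera adjusted p = 0.125). WNT pathway genes had NKD2 higher and FZD3 and FZD7 lower of 29 (2 and 5 adjusted over the list alone; camera adjusted p = 0.256), and p53 targets had TP53I3 higher of 22 (1 adjusted over the list alone; camera adjusted p = 0.987). Of 28 hypoxia and glycolysis genes CA9 was higher (1 adjusted over the list alone), with no counts in wild type and at least 4.89-fold higher (camera adjusted p = 0.164). CA9 was not called with limma-trend on TPM (adjusted p = 0.0947) or effective length offsets (0.0627), nor against a 1.2-fold change (0.0522), and DESeq2 gave it no adjusted p. Numbered zinc finger genes had 9 higher, including ZNF726 (2.18), and 18 lower, including ZNF671 (-3.87), of 418 (14 and 25 adjusted over the list alone; camera adjusted p = 0.0919). Among 17 endoplasmic reticulum stress, 13 mitochondrially encoded and 5 blood cell genes none was called over all genes by edgeR (0, 2 and 2 adjusted over the list alone; 5, 4 and 3 at an unadjusted p under 0.05; DESeq2 called 1, 1 and 2; camera adjusted p = 0.262, 0.0692 and 0.164). Of the protocadherins 4 alpha, 1 beta and 4 gamma genes were tested and none was called over all genes by edgeR (0, 0 and 1 adjusted over the list alone; 1, 0 and 1 at an unadjusted p under 0.05), and of 4 hepatocyte markers FGG was called (2 adjusted over the list alone), at 0.877 CPM in mutant.

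Gene span had little relation to fold change. Across 14443 protein-coding genes the Spearman correlation was 0.070, across genes, which are not independent replicates. Span correlated at -0.114 with wild-type replicate 2 minus 1 and at 0.048 with mutant replicate 2 minus 1. The relation to fold change was thus weaker than that to the difference between the wild-type replicates. In the fifth of genes with the longest span 6.68% were higher, against 3.53% to 4.26% in the other 4 groups of like size, and the median log2 fold change there was 0.08. The correlation was 0.020 without wild-type replicate 2 and 0.017 with effective length in place of span.

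Fold changes followed chromosome position. Genes on chromosomes 8, 4 and 7 had medians of -0.29, -0.23 and -0.16 less that of all tested protein-coding genes, and those on chromosomes 17, X and 3 had 0.22, 0.13 and 0.12. These 6 were called by camera (adjusted p = 7.43e-07, 0.000578, 0.0193, 0.000221, 0.00109 and 0.0223), and none with an estimated correlation (lowest adjusted p = 0.0889 with an estimated correlation). Chromosome 3 was not called without wild-type replicate 1 (adjusted p = 0.226) or mutant replicate 1 (0.0658), nor chromosome 7 without mutant replicate 1 (0.0554). Of 14420 adjacent gene pairs 127 were both called in 1 direction, against a mean of 51.9 and a maximum of 75 in 1000 permutations (permutation p = 0.001, one-sided, the smallest they can give). Of 11942 pairs that do not overlap, an alternative added after seeing the data, 112 were, against a mean of 43.7.

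Within chromosomes the shifts ran over long stretches, picked out after seeing the data. On chromosome 2, the 397 genes from 0 to 90 Mb had a median log2 fold change of 0.38 and the 519 genes from 100 to 250 Mb one of -0.45, with 90 of the 359 lower protein-coding genes. The 100 genes on chromosome 3 from 180 to 200 Mb had a median of 0.67, with 29 higher and none lower by edgeR. The 104 genes on chromosome 5 from 0 to 50 Mb, which hold NIPBL, had 0.42. Wild-type replicate 2 minus 1 gave 0.07, 0.03, -0.06 and -0.04 over these stretches. Of 280 regions 82 were called by camera at its preset correlation. Regions were not tested with an estimated correlation, under which no chromosome was called, so these calls may not hold there. When 52 regions were called on every other gene, they held 40.9% of the lower and 35% of the higher calls among the genes left out, against 18.4% of all genes left out.

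**Figure D3:**
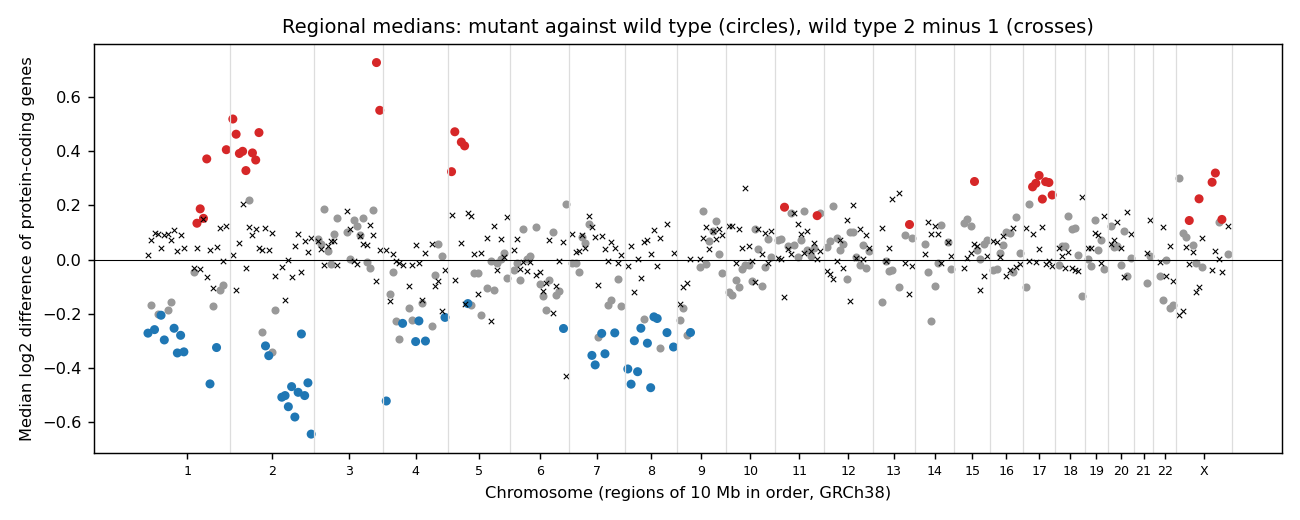
Median log2 difference of tested protein-coding genes in 280 regions of 10 Mb along the genome, for mutant against wild type (circles; red called up, blue called down, grey not called) and for wild-type replicate 2 minus 1 (crosses). Regions called by camera at its preset correlation run together on chromosomes 1, 2, 5, 7, 8 and 17, among others. The SD over regions is 0.218 for the circles and 0.088 for the crosses.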

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

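The neighbourhood offset and the pairs that do not overlap were chosen after seeing the data. Fits without a wild-type replicate take their spread from the close mutant pair alone, so a call kept there adds little support. Those without a mutant replicate take it from the wider wild-type pair alone, so a call lost there need not mean dependence on that library. Of 72 called named genes 41 and 39 stayed called without mutant replicate 1 or 2, 71 without each wild-type replicate, 53 with limma-trend on TPM and 44 with the neighbourhood offset. Leaving out 1 library at a time gave from 335 to 5909 higher and from 64 to 5931 lower genes, NIPBL from 0.45 to 0.55, from 24 to 3981 adjacent pairs (from 3.08 to 1.13 times the permuted mean, against 2.45 with all libraries), and the span correlation from 0.020 to 0.090. The labels do not say whether same-numbered libraries were paired. Deviations of same-numbered libraries correlated at -0.059 over genes, which cannot settle it with 2 libraries per group. The replicate block gave 1470 higher and 809 lower genes and 342 adjacent pairs (1.83 times).

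Total counts gave 1112 higher genes, 204 pairs (2.03 times) and NIPBL at 0.69; upper-quartile scaling gave NIPBL at 0.60. No filter gave 1132 higher, 786 lower and 242 pairs (2.06 times), with 33495 genes tested. The stricter filter gave NIPBL at 0.53. DESeq2 gave 1230 higher, 1116 lower, 330 pairs (1.83 times) and NIPBL at 0.50. Limma-trend on TPM gave 119 lower genes. The test against a 1.2-fold change ended the call of 20 of the 72 named genes and gave 386 higher, 134 lower and 40 pairs (3.29 times). The neighbourhood offset gave 443 higher and 167 lower genes, 41 pairs (3.02 times), a span correlation of 0.099 and 0 chromosomes called, the last by its construction. Effective length in place of span gave a correlation of 0.017, and an estimated correlation left 0 of 17 lists called. The cause of the other changes was not tested.

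Of the 1103 called genes 6 changed sign with the neighbourhood offset, among them RFC4 (-0.11), and 1 on TPM. The called G1/S list had a median of 0.073 with total counts and 0.078 on TPM. The following were not called by edgeR or camera in the planned tests. With upper-quartile scaling the cohesin list had 0.020 and SGO1 0.052. With total counts the list had 0.11, RAD21 0.015, HDAC8 0.011, WAPL 0.003, CDCA5 0.075 and SGO1 0.14. On TPM the list had 0.11, RAD21 0.006, WAPL 0.037, CDCA5 0.11 and SGO1 0.11. With the stricter filter camera's direction for the cohesin list turned from down to up, while its median stayed negative (-0.052, against -0.07 in the main fit). RAD21 had 0.004 with the neighbourhood offset. Leaving out 1 library gave CTCF from -0.55 to 0.006, WAPL from -0.37 to 0.027, CDCA5 from -0.29 to 0.085 and SGO1 from -0.20 to 0.13. It gave list medians from -0.175 to 0.056 for cohesin, -0.177 to -0.003 for Mediator, -0.079 to 0.201 for p53 targets and -0.409 to -0.046 for endoplasmic reticulum stress. For p53 targets camera's direction was up in the main fit, at a list median of -0.054 (camera adjusted p = 0.987). It was down with no filter (median -0.069), the stricter filter (-0.14), limma-voom (-0.047), small RNA left out (-0.057) and the neighbourhood offset (0.13). Only the last of these medians differed in sign from the main fit.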

Other observations

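All tests in this part were chosen after the results were seen. Calls among the least expressed genes were lopsided. Among the 2889 protein-coding genes with the lowest mean level over all libraries, 307 were higher and 23 lower in mutant, while among the other 11554 genes 335 were higher and 336 lower. From under 1 CPM in wild type to at least 1 CPM in mutant went 603 tested genes, and 110 went the other way.

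Broad stretches of chromosomes shifted together. A GC content and gene length trend is argued against by 90 regions called from the test statistics of single genes, a different test from that of the report. Of these 91.1% stayed called once that trend was removed. A difference in DNA copy number between the cultures may account for the stretches: among genes left out of the calling, 77.2% shared the direction of their region (72.1 to 80.6% when the 13 chromosomes concerned were resampled, since neighbouring genes are not independent). All of these genes come from the same 4 libraries. Regional control of transcription by genotype would give the same share and stays open, as no DNA measurement was analysed here and the labels do not state the number of clones.

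The wild-type libraries differed in stress and growth lists by more than the mutant libraries did. A GC content and gene length trend does not account for most of it in the lists tried. Once that trend was removed, the ATF4 median (wild-type replicate 2 minus 1) went from -1.15 to -1.21. The heat shock median went from 0.75 to 0.66 and the ribosome biogenesis median from 0.66 to 0.58. A mutant culture labelled as wild type is argued against by chromosome 3 from 180 to 200 Mb, where the wild-type libraries differed by -0.055 and mutant from wild type by 0.67. A difference in growth or stress state between the wild-type cultures may remain and was not tested.

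Of 1644 tested protein-coding genes under 1 CPM in wild type, 272 were called higher and 7 lower in mutant. A gene this low in wild type can pass the filter through its mutant level. Choosing genes by a low wild-type level thus favours higher calls, and the pattern is partly built in. Squamous epithelial cells in the mutant cultures are argued against, since KRT5, KRT14 and KRT6A together had 2 counts there against 1020 for KRT17. Fibroblasts in the mutant cultures are argued against by COL1A2, with 0 counts there against 484 for COL1A1. An equal addition of background reads to every gene is argued against as the whole cause. The 376 olfactory receptor genes together went from 27 and 29 counts in wild type to 43 and 45 in mutant, a rise of 0.0013 CPM per gene, while the median rise of the called higher genes under 1 CPM in wild type was 1.43 CPM. The whole mutant level of the receptor genes was at most 0.0045 CPM per gene (exact Poisson bound). A small rise of background is not excluded. Other cell types, selection of a clone and an effect of the genotype may each remain, untested.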
